A study of Homo sapiens with 12 samples.

How the data were processed

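Messenger RNA was sequenced from HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. The 12 libraries formed 4 groups of 3, each transfected with a guide RNA set for 4 sites at IL1RN and with plasmid for dCas9 alone, dCas9-VP64, dCas9-p300 core or dCas9-p300 D1399Y. Per the submitters' processing notes, the authors deposited 1 table of raw read counts per library, with hg19 as the genome build and CASAVA, Bowtie2, SAMtools, R 3.1.2 and DESeq2 1.6.2 as the tools; the step each tool served, and the versions of the first 3, are not given in the sources used here. The deposited values are counts in whole numbers for 40709 RefSeq transcripts, with the isoforms of a gene listed apart. The rule for reads shared by isoforms, the strand setting and the handling of duplicate reads are not given in the sources used here. The highest count per base of any transcript lay between 0.781 and 1.68 over the 12 libraries, and ACTB took 0.0180% to 0.0319% of the counts. Whether reads of abundant transcripts were limited, as by removal of duplicates, is not given in the sources used here. Such a limit could narrow their fold changes or, between libraries of unlike depth, shift them one way.

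Transcripts were named through a RefSeq table (39324 transcripts) and GENCODE (516 transcripts), and 869 transcripts holding 1.07% of the reads kept their identifier as a name. Counts were summed over the transcripts of a gene, which left 24395 features, 23526 of them named genes. Both naming tables belong to the GRCh38 assembly while the counts rest on hg19, so no coordinates are given, and only the chromosome and the order of genes on it were taken from GRCh38. Total counts per library ran from 2442960 to 5154627.

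Differences were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr (a minimum count of 10 and a minimum total of 15), and the quasi-likelihood test, in 1 fit of group means over all 12 libraries. The filter kept 14613 genes. Tests were two-sided, adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05 on the adjusted p. Levels are in CPM, the edgeR scale of counts relative to TMM-scaled library sizes, and errors beside a log2 fold change are standard errors. Each of 5 comparisons was made over all genes, and IL1RN was also compared between dCas9-VP64 and D1399Y, which gave 6 IL1RN comparisons. The groups, comparisons, test, gene lists and the rule for named genes were chosen before the data were examined.

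The 23 gene lists hold 361 genes, of which 345 were in the files. The 13 mitochondrially encoded genes, NT5DC4, CECR2 and HIST1H2BC were not analysed here. Lists with at least 3 tested members, 20 in all, were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, on log2 CPM with a prior count of 2, and again with an estimated correlation and with fry, adjusted over the lists of each comparison. fry tests whether the members of a list move one way on balance and compares them with no other genes. Genes named in the text are IL1RN, EP300, the tested neighbours of IL1RN, genes past the threshold (at most 12 each way), the 5 genes of smallest unadjusted p that did not pass where fewer than 10 passed, and at most 4 members of each list by unadjusted p. Of the genes this rule selects, 4 are not reported here, and they stayed in the fits and the list tests.

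Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter, a stricter filter (1 CPM in 6 libraries), the replicate number as a block, fits of the compared groups alone, the CV41 libraries alone, the pool label as a covariate, and leaving out each library in turn. The labels give a pool name, CV41 for 10 libraries and CV42 for replicate 3 of both p300 groups. After the data were examined, a robust quasi-likelihood fit, limma-voom with quality weights, offsets for transcript length and GC content, a fit without ribosomal RNA and a fit of single transcripts were added. Length and GC content were at hand for 13778 tested genes (94.3%), and the trend was drawn over 12172 genes with a mean count of at least 20. Simulated data held known changes in the core against dCas9 comparison. There the edgeR test recovered 58.2% of 67 genes changed 2-fold and 94.0% of 67 genes changed 4-fold, with 11 false calls among 178. DESeq2 made 23 false calls among 193. The simulation drew genes independently, and its many calls ease the cutoff on unadjusted p. With 0 or 1 calls in the real comparisons the cutoff was stricter, so these shares do not measure the power there. Software was Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 beside R.

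The labels state only that cells were transfected in triplicate, so p-values measure the spread between these samples alone. Intervals on a single library's count cover counting error only, since reads without molecular identifiers are not independent molecules.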

Results

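Polyadenylated RNA was sequenced from HEK293T cells that had received guide RNAs for 4 sites at IL1RN together with 1 of 4 proteins. IL1RN encodes the interleukin 1 receptor antagonist, a secreted protein that blocks the interleukin 1 receptor. The proteins were dCas9, which binds DNA without cutting it, and dCas9 fused to VP64, a viral transcriptional activation domain, to the catalytic core of the histone acetyltransferase p300, or to that core with the D1399Y change, which removes its acetyltransferase activity. Each group held 3 libraries. Total counts ran from 2442960 in dCas9 replicate 3 to 5154627 in dCas9-p300 core replicate 2, and the other 10 libraries lay between them. The comparisons ask how far each protein altered IL1RN RNA and which other genes differed.

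IL1RN RNA was highest in the p300 core group. Its mean level was 6.74 ± 2.51 CPM (SD, n = 3) with dCas9, 24.7 ± 6.07 CPM with dCas9-VP64, 83.6 ± 8.64 CPM with dCas9-p300 core and 7.78 ± 1.42 CPM with dCas9-p300 D1399Y. The counts behind these levels were 15, 28 and 25 in the dCas9 libraries, 95, 76 and 123 with dCas9-VP64, 278, 455 and 339 with the core, and 24, 26 and 35 with D1399Y. All 3 core libraries exceeded the 9 others, and all 3 dCas9-VP64 libraries exceeded the 6 libraries of the dCas9 and D1399Y groups.

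**Figure D1:**
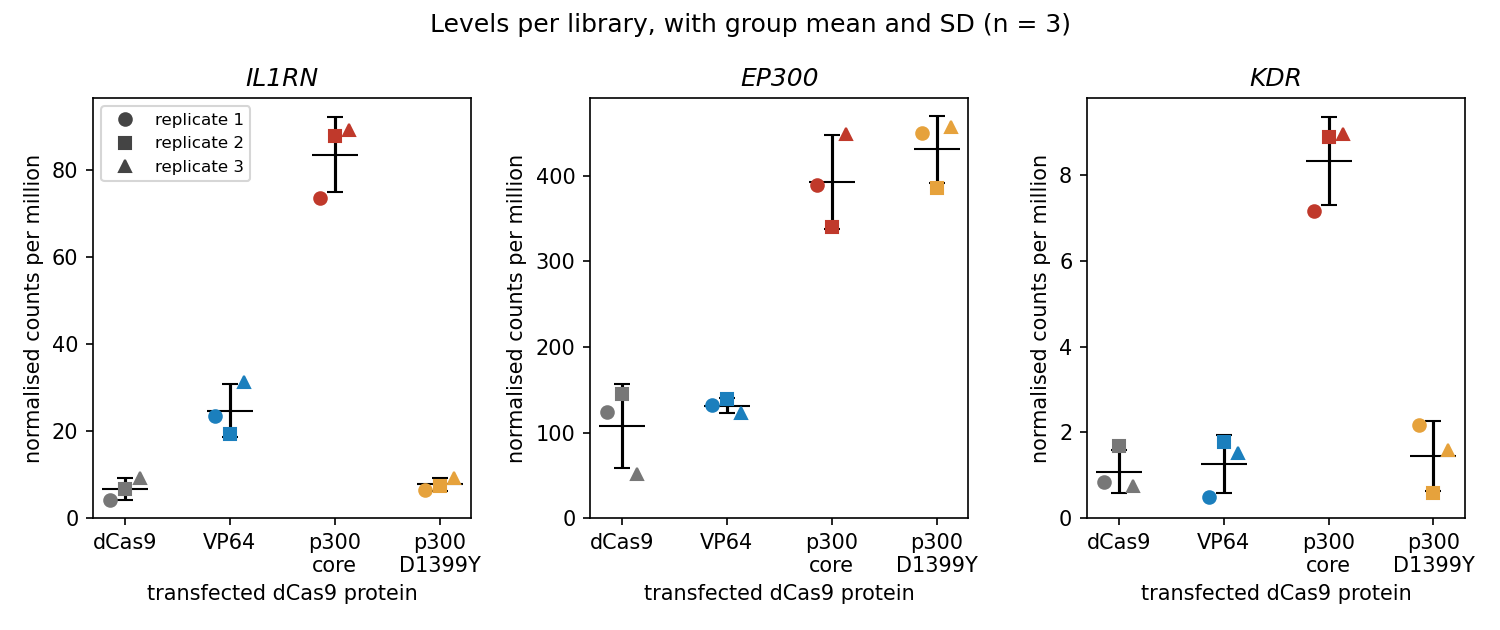
Normalised levels of IL1RN, EP300 and KDR (CPM) in each library of the 4 groups, with points for libraries and the mean with its SD. The 3 core libraries hold the highest IL1RN levels, with a mean of 83.6 CPM, and EP300 is highest in the libraries of both p300 groups.

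The comparison of dCas9-VP64 with dCas9 shows what the activation domain added at the same guide sites. IL1RN was 3.73-fold higher with dCas9-VP64 (95% interval 2.52 to 5.53; log2 1.90 ± 0.26), in 3 of 3 libraries, and this did not pass the test over all genes (adjusted p = 0.0749, edgeR). Adjusted over the 6 IL1RN comparisons alone, its adjusted p was 7.69e-06. The other genes of smallest p were BCLAF1 (log2 0.66 ± 0.16), a regulator of transcription and splicing, C1orf210 (log2 -1.78 ± 0.44), NIPBL-DT (log2 0.55 ± 0.14), a noncoding transcript divergent from NIPBL, and TMEM185B (log2 0.59 ± 0.16), each at an adjusted p of 0.929. EP300 stood at log2 0.28 ± 0.26.

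Among the 20 gene lists tested in that comparison, camera placed 7 lower and 0 higher with dCas9-VP64. The cytosolic ribosomal protein genes had 1 of 30 members above 0 and a median log2 of -0.23, with RPL11 at -0.32 ± 0.18 and RPL3 at -0.28 ± 0.15 (adjusted p = 2.33e-08). Heat shock genes had 0 of 11 members above 0 and a median of -0.23, with the chaperones HSPA1A at -0.65 ± 0.36 and HSPA1B at -0.57 ± 0.30. Immediate early genes had 2 of 17 members above 0, with JUNB, an AP-1 subunit, at -0.52 ± 0.23 and the clock gene PER1 at -0.43 ± 0.21. Histone genes had 1 of 9 above 0, with the linker histone gene H1-2 at -1.01 ± 0.39 and H4C3 at -0.74 ± 0.45. Cholesterol synthesis genes had 2 of 14 above 0, with FDFT1, squalene synthase, at -0.30 ± 0.14 and MVD, mevalonate diphosphate decarboxylase, at -0.61 ± 0.29. Genes of the response to unfolded protein had 2 of 16 above 0, with the stress factor DDIT3 at -0.55 ± 0.25 and the chaperone CALR at -0.26 ± 0.15, and the list shared an adjusted p of 0.00506 with the heat shock, immediate early, histone and cholesterol lists. Hypoxia targets had 2 of 16 above 0, with the glycolytic enzyme gene ALDOA at -0.42 ± 0.17 and the collagen hydroxylase gene P4HA1 at -0.43 ± 0.25 (adjusted p = 0.00570). None of the 7 calls held otherwise: adjusted p = 0.577 for each with an estimated correlation, and adjusted p = 0.611 for each with fry. A limit on reads could have narrowed or shifted the values of abundant transcripts, ribosomal and heat shock genes among them. Whether such a limit was placed is not given in the sources used here. No member of any list passed over all genes, and 0 passed adjusted over the list alone. The endothelial list had a median of 0.09 with a mean of -0.10 and a test direction of lower, and the fibroblast list a median of -0.11 with a mean of 0.21 and a test direction of higher.

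dCas9 replicate 3 stood apart from all other libraries, and several of these lists moved with it. Its median log2 ratio to the mean of the 12 libraries was 0.48 for ribosomal protein genes, 0.28 for the unfolded protein list and 0.25 for heat shock genes. In dCas9 replicate 1 it was 0.74 for histone genes, 0.60 for hypoxia targets, 0.35 for heat shock genes, 0.30 for immediate early genes and 0.28 for cholesterol synthesis genes. The ribosomal ratio was highest in dCas9 replicate 3, the library of lowest total count (2442960). It was lowest, at -0.26, in core replicate 2, the library of highest total count (5154627). Whether depth moved the ribosomal values was not tested. Of the 7 lists called for dCas9-VP64, 2 remained without dCas9 replicate 1 and 4 without dCas9 replicate 3. Leaving out replicates 1, 2 and 3 of dCas9-VP64 kept 6, 4 and 5 of them. Without dCas9 replicate 3 the ribosomal, heat shock and unfolded protein calls were lost, at medians of -0.07, -0.13 and -0.04. Without dCas9 replicate 1 the hypoxia, heat shock, immediate early, histone and cholesterol calls were lost, at medians of -0.04, -0.09, -0.14, -0.16 and -0.11. With offsets for length and GC content the ribosomal median was -0.09 with its call kept, and the histone call alone was lost, at a median of -0.18. The offsets added calls of lower for bromodomain proteins, at -0.11, and proliferation genes, at -0.12. Targets of p53 were called higher with the offsets and without dCas9 replicate 3, at medians of 0.14 and 0.15.

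Across all 14613 genes, edgeR placed 0 genes past the threshold for dCas9-VP64 against dCas9. DESeq2 placed 1 gene past it, IL1RN, and limma-voom 0. In edgeR 449 genes had an unadjusted p under 0.05, where 730.7 would be expected by chance. Over the alternatives that count ran from 163, in the fit of the compared groups alone, to 1897, without dCas9 replicate 2. It is therefore no measure of how many genes changed. In edgeR IL1RN passed without dCas9 replicate 3 (log2 2.15, adjusted p = 0.00832) and with the replicate number as a block (log2 1.89, adjusted p = 0.0232). It also passed there without a filter (adjusted p = 0.0145) and with length and GC offsets (adjusted p = 0.0176). Over all alternatives its adjusted p ran from 5.01e-07 to 0.998.

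The comparison of dCas9-p300 core with dCas9 shows what the acetyltransferase core added. IL1RN was 12.6-fold higher with the core (95% interval 8.60 to 18.5; log2 3.66 ± 0.26; adjusted p = 1.85e-05, edgeR), in 3 of 3 libraries, and was the 1 gene past the threshold. EP300, the gene of p300 itself, was 3.63-fold higher (log2 1.86 ± 0.27; adjusted p = 0.0520) and KDR, the receptor VEGFR2, 7.13-fold higher (log2 2.83 ± 0.42; adjusted p = 0.0520), and both missed the threshold narrowly. Both p300 plasmids carry the p300 core, so EP300 counts in both p300 groups can include reads of the plasmid. The EP300 values here and below are therefore no measure of the cell's own gene. KDR stood at 1.09 ± 0.510 CPM with dCas9 and 8.33 ± 1.02 CPM with the core (SD, n = 3). Next in order were CYRIA, a regulator of the actin regulator Rac1 (log2 2.15 ± 0.38; adjusted p = 0.262), DPF3, a subunit of the BAF chromatin remodelling complex (log2 1.84 ± 0.36), and NFASC, the adhesion protein neurofascin (log2 1.32 ± 0.26), the last pair each at an adjusted p of 0.479.

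All 4 IL1RN transcripts listed in the files rose with the core in a fit of 25610 single transcripts. The log2 fold changes were 3.51 ± 0.32 for NM_173841, 3.55 ± 0.30 for NM_173842, 3.53 ± 0.32 for NM_000577 and 3.96 ± 0.32 for NM_173843, with adjusted p from 5.56e-05 to 8.87e-05 (edgeR). Their counts lay close together, with 68, 67, 74 and 69 in core replicate 1, although their lengths ran from 848 to 1922 bases. How reads shared by isoforms were counted is not given in the sources used here, so these values are no separate measures of the isoforms.

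The tested genes around IL1RN on chromosome 2 did not pass the test. In GRCh38 order, PSD4 lies 1 protein-coding gene from IL1RN, and its log2 fold change with the core was 0.35 ± 0.45. ZNG1B lies 3 and RABL2A 7 genes away on the same side. On the other side the tested genes run from CKAP2L, at -9, to TTL, at -14. ZNG1B stood at 0.04 ± 0.18, RABL2A at 0.39 ± 0.33, CKAP2L at 0.24 ± 0.23, SLC20A1 at -0.08 ± 0.12, CHCHD5 at -0.20 ± 0.25, POLR1B at 0.12 ± 0.17 and TTL at 0.20 ± 0.12. In edgeR 0 of these 8 genes passed in any of the 5 comparisons, over all genes or adjusted over the list alone, and the smallest adjusted p over the list was 0.439, against D1399Y with dCas9; 0 passed under each of 26 alternatives, which included DESeq2 and limma-voom. The cytokine genes IL37, IL36G, IL36A, IL36RN, IL36B and IL1F10 had 0 counts in all 12 libraries, and IL1A and IL1B had 2 counts each in all. A fall in them, or a small rise, was not detectable at this depth. In the core libraries no rise was seen in them beyond 2 counts of IL1B in core replicate 2.

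Among the gene lists, camera placed 6 lower and 1 higher with the core. Ribosomal protein genes had 0 of 30 members above 0 and a median log2 of -0.28, with RPS12 at -0.38 ± 0.17 and RPLP2 at -0.34 ± 0.16 (adjusted p = 3.70e-12). Heat shock genes had 0 of 11 above 0 and a median of -0.24, with the chaperones HSP90AA1 at -0.27 ± 0.14 and HSPE1 at -0.38 ± 0.22 (adjusted p = 0.00601). Histone genes had 1 of 9 above 0 and a median of -0.40, with the linker histone gene H1-2 at -0.72 ± 0.38. The unfolded protein list had 1 of 16 above 0 and a median of -0.13, with PPP1R15A, a regulatory subunit of the eIF2 alpha phosphatase, at -0.35 ± 0.18 and DDIT3 at -0.43 ± 0.24, at the same adjusted p of 0.0161 as the histone list. Immediate early genes had 4 of 17 above 0, with JUNB at -0.66 ± 0.23 and IER3 at -0.49 ± 0.35, and proliferation genes 6 of 22 above 0, with the replication clamp PCNA at -0.23 ± 0.14 and the replication licensing gene CDC6 at -0.16 ± 0.12, each list at an adjusted p of 0.0291. The endothelial list was higher (adjusted p = 0.0295) with 3 tested members, a median of 0.16 and a mean of 0.99, and KDR was its 1 member past the threshold adjusted over the list alone (adjusted p = 3.20e-05), with FLT1, the receptor VEGFR1, at 0.16 ± 0.24. All 7 calls were lost otherwise: adjusted p = 0.544 for each with an estimated correlation, and adjusted p from 0.0587 to 0.566 with fry.

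In the fit of all libraries the other 13 lists did not pass, and 0 of their members passed over all genes or adjusted over the list alone. Interferon-stimulated genes had a median of 0.09, with the antiviral enzyme gene OAS3 at 0.96 ± 0.34. Genes of interleukin 1 receptor signalling, the pathway that the IL1RN product blocks, had a median of 0.13, with the kinase IRAK4 at 0.31 ± 0.15 and the receptor IL1R1 at 0.58 ± 0.43. NF-kB targets had a median of -0.02, with the inhibitor NFKBIA at -0.32 ± 0.15. Other histone acetyltransferases had a median of 0.20, with TAF1 at 0.39 ± 0.21 and HAT1 at -0.20 ± 0.14, histone deacetylases a median of -0.06, with HDAC10 at -0.64 ± 0.31 and HDAC9 at 0.90 ± 0.47, and bromodomain proteins a median of 0.06. Medians were -0.09 for p53 targets, with BBC3, the apoptosis gene PUMA, at -0.55 ± 0.22, and -0.15 for hypoxia targets, with ENO1 at -0.27 ± 0.15. The hypoxia list had 1 of 16 members above 0 and missed the threshold narrowly (adjusted p = 0.0531). It was called lower within the CV41 libraries and without core replicate 1, core replicate 3, dCas9 replicate 2 or dCas9 replicate 3, at medians of -0.22, -0.22, -0.22, -0.32 and -0.21. Targets of p53 were called lower without core replicate 1, at a median of -0.19. Marker lists had medians of 0.23 for fibroblasts, with COL6A3 at 1.58 ± 0.65, of -0.15 for keratinocytes and epithelium, with EPCAM at -0.43 ± 0.39, and of -0.11 for neuronal and renal lineages. The list of IL1RN neighbours had a median of 0.16. Cholesterol synthesis genes had a median of 0.02 with a mean of -0.04 and a test direction of lower, and among lists too small for the test LYZ stood at -0.44 ± 0.27 and the pluripotency factor POU5F1 at -0.12 ± 0.27.

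In edgeR 454 genes had an unadjusted p under 0.05 for the core against dCas9, where 730.7 would be expected by chance. At an unadjusted p under 0.001, 11 genes were higher and 0 lower, where 14.6 would be expected. As the first count already fell short of its expectation, the second does not show that these 11 genes arose by chance. DESeq2 placed 4 genes past the threshold (IL1RN, EP300, KDR and CYRIA) and limma-voom 2 (IL1RN and EP300). EP300 passed without dCas9 replicate 2 (log2 2.14, adjusted p = 0.0305) and without dCas9 replicate 3 (log2 1.54, adjusted p = 3.22e-05), where the count was 2 genes each time. Within the CV41 libraries, which hold 2 of the 3 core libraries, IL1RN stood at log2 3.61 ± 0.29 (adjusted p = 0.000652) and EP300 at log2 1.75 ± 0.31 (adjusted p = 0.621); the CV42 libraries hold none of the dCas9 group.

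Several of the 7 lists called for the core stood apart in single dCas9 libraries. In dCas9 replicate 3 the median log2 ratio to the mean of the 12 libraries was 0.48 for ribosomal protein genes, 0.28 for the unfolded protein list, 0.17 for proliferation genes and -0.99 for the endothelial list. In dCas9 replicate 1 it was 0.74 for histone genes, 0.35 for heat shock genes and 0.30 for immediate early genes. Of the 7 lists, 2 remained without dCas9 replicate 1, 6 without dCas9 replicate 2 and 4 without dCas9 replicate 3, and 5, 2 and 6 without core replicates 1, 2 and 3. Without dCas9 replicate 1 the heat shock, histone, immediate early and proliferation calls were lost, at medians of -0.09, -0.19, -0.05 and -0.12. Without dCas9 replicate 3 the proliferation and unfolded protein calls were lost, at -0.05 and -0.06. Without core replicate 1 the immediate early and unfolded protein calls were lost, at -0.12 and -0.13. Without core replicate 2 the heat shock, histone, immediate early, proliferation and unfolded protein calls were lost, at -0.19, -0.36, -0.13, -0.05 and -0.12. The ribosomal call was kept in each of these fits, with a median of -0.12 without dCas9 replicate 3 and -0.08 with offsets for length and GC content. The endothelial call was lost within the CV41 libraries and without any of dCas9 replicates 1, 2 and 3 or core replicate 3, at medians of 0.19, 0.24, 0.42, -0.03 and 0.19, and with the offsets, at a median of -0.02. The offsets also ended the histone, immediate early and unfolded protein calls, at medians of -0.35, -0.20 and -0.11, and 3 of the 7 calls remained. With them bromodomain proteins were called lower, at a median of -0.12.

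**Figure D2:**
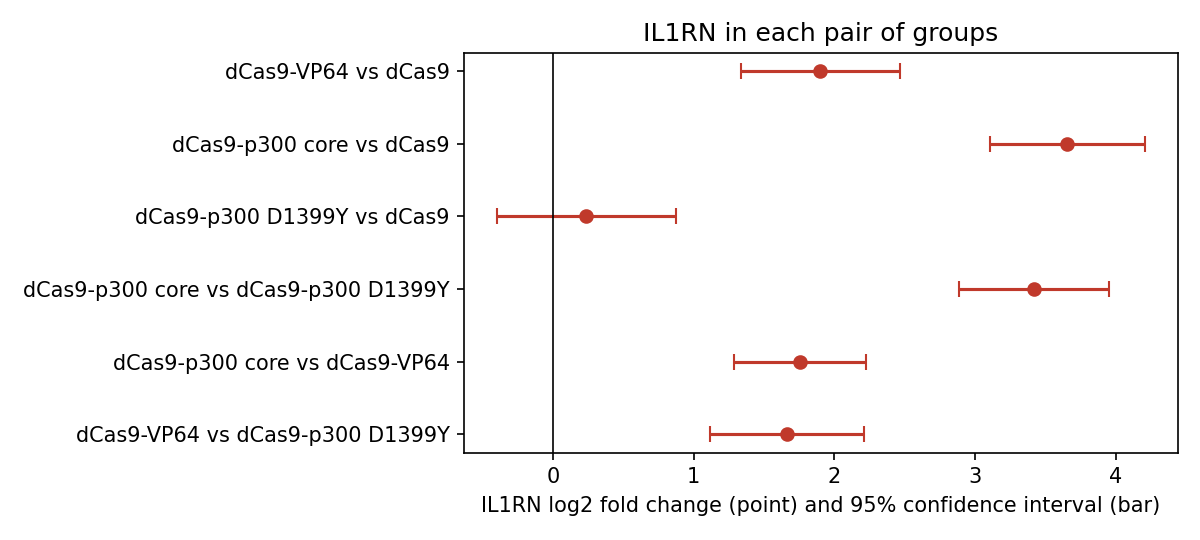
Log2 fold change of IL1RN in each of the 6 comparisons, with points for the edgeR estimate and bars for its 95% interval. The estimates run from 0.24 for D1399Y against dCas9 to 3.66 for the core against dCas9.

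The comparison of dCas9-p300 D1399Y with dCas9 shows what remained without acetyltransferase activity. IL1RN did not differ detectably, at 1.18-fold (95% interval 0.758 to 1.83; log2 0.24 ± 0.30; adjusted p = 0.732, edgeR), and the interval excludes the 12.6-fold found with the core. Without dCas9 replicate 1 its log2 fold change was -0.02. EP300 was 3.99-fold higher (95% interval 2.68 to 5.95), in 3 of 3 libraries, and narrowly missed the threshold (adjusted p = 0.0515). Its level was 107 ± 49.2 CPM with dCas9 and 431 ± 38.9 CPM with D1399Y (SD, n = 3). The other genes of smallest p were NIPBL-DT (log2 0.64 ± 0.14), the choline transporter-like gene SLC44A4 (log2 -0.97 ± 0.25), HAUS8, a subunit of the augmin complex of the spindle (log2 -0.76 ± 0.20), and the unnamed transcript NM_001270493 (log2 1.29 ± 0.33), each at an adjusted p of 0.632.

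Camera placed 3 of 20 lists lower with D1399Y and 0 higher. Ribosomal protein genes had 0 of 30 members above 0 and a median log2 of -0.19, with RPS9 at -0.31 ± 0.18 and RPL30 at -0.27 ± 0.17 (adjusted p = 0.000631). Heat shock genes had 0 of 11 above 0 and a median of -0.24, with the chaperone HSPB1 at -0.49 ± 0.24 and its partner BAG3 at -0.34 ± 0.18 (adjusted p = 0.0412), and histone genes 0 of 9 above 0 and a median of -0.50, with H4C3 at -1.22 ± 0.49 and H2AC18 at -1.01 ± 0.39 (adjusted p = 0.0173). Each call was lost otherwise: adjusted p = 0.769 with an estimated correlation and adjusted p = 0.694 with fry. In dCas9 replicate 3 the median log2 ratio to the mean of the 12 libraries was 0.48 for ribosomal protein genes and 0.25 for heat shock genes, and in dCas9 replicate 1 it was 0.74 for histone genes and 0.35 for heat shock genes. LYZ, the lysozyme gene, was the 1 list member past the threshold adjusted over the list alone (log2 -1.12 ± 0.30; adjusted p = 0.00420, in a list with 2 tested genes), and it did not pass over all genes (adjusted p = 0.632). Median and mean differed in sign for 5 lists, with medians of -0.02 for bromodomain proteins, 0.02 for interferon-stimulated genes, 0.05 for keratinocyte markers, 0.05 for NF-kB targets and 0.00 for p53 targets, beside means of 0.04, -0.01, -0.17, -0.07 and -0.13, whose sign the test shared.

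EdgeR placed 0 genes past the threshold for D1399Y against dCas9, with 861 at an unadjusted p under 0.05, and DESeq2 and limma-voom each placed 1, EP300. EP300 passed in edgeR without dCas9 replicate 2 (log2 2.28, adjusted p = 0.0335) and without dCas9 replicate 3 (log2 1.67, adjusted p = 1.96e-05). Within the CV41 libraries it stood at log2 1.96 ± 0.31 (adjusted p = 0.612) and IL1RN at log2 0.08 ± 0.35 (adjusted p = 0.920). Of the 3 lists, 1 remained without dCas9 replicate 1, without dCas9 replicate 3, without D1399Y replicate 3 and within the CV41 libraries. In turn 2 remained without dCas9 replicate 2, without dCas9-VP64 replicate 2, without D1399Y replicate 2 and without core replicate 3. The heat shock call was lost in all of these fits except the fit without dCas9 replicate 2. The histone call was lost without dCas9 replicate 1 or 2, without D1399Y replicate 3 and within the CV41 libraries. The ribosomal median turned to 0.05 with offsets for length and GC content, with 19 of 30 members above 0, and was -0.02 without dCas9 replicate 3, with 11 of 30 above 0, and its call was lost both times. The offsets also ended the histone call, at a median of -0.32, and 1 of the 3 calls remained. With the offsets bromodomain proteins were called lower, at a median of -0.13. Hypoxia targets were called lower without dCas9 replicate 2 or 3, at medians of -0.38 and -0.27, and the unfolded protein list without D1399Y replicate 2, at -0.15.

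The comparison of dCas9-p300 core with D1399Y isolates the acetyltransferase activity. IL1RN was 10.7-fold higher with the active core (95% interval 7.38 to 15.5; log2 3.42 ± 0.25; adjusted p = 2.96e-05, edgeR), in 3 of 3 libraries, and was the 1 gene past the threshold. KDR was 5.60-fold higher without passing (log2 2.49 ± 0.40; adjusted p = 0.171), and EP300 differed by log2 -0.14 ± 0.26 (95% interval -0.685 to 0.414). The other genes of smallest p were DHRS2, a short-chain dehydrogenase (log2 2.65 ± 0.48; adjusted p = 0.357), the cyclic nucleotide phosphodiesterase PDE2A (log2 2.03 ± 0.38), CRISPLD2, a secreted protein (log2 1.78 ± 0.34), and DCAF4L1 (log2 1.63 ± 0.32), the last 3 each at an adjusted p of 0.398.

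Camera placed 1 of 20 lists lower in the core against D1399Y comparison and 0 higher. It was the ribosomal protein list, with 2 of 30 members above 0, a median log2 of -0.08, RPL15 at -0.14 ± 0.12 and RPL27 at -0.16 ± 0.14 (adjusted p = 0.0144; adjusted p = 0.946 with an estimated correlation, adjusted p = 0.997 with fry). That call was lost without core replicate 2, core replicate 3, D1399Y replicate 1 or D1399Y replicate 3, at medians of -0.02, -0.07, -0.06 and -0.07, and within the CV41 libraries, at -0.04. Without core replicate 2, 11 of 30 members were above 0. The call was kept without core replicate 1, at a median of -0.20, without D1399Y replicate 2, at -0.13, and with offsets for length and GC content, at -0.14. KDR passed adjusted over the endothelial list alone (adjusted p = 7.03e-05), a list with a median of -0.03, a mean of 0.80 and a test direction of higher (adjusted p = 0.235). The endothelial list was called higher without D1399Y replicate 2, at a median of 0.17, and with the offsets, at 0.09, and p53 targets were called lower without core replicate 1, at -0.10. The test direction was lower against a mean of 0.02 for heat shock genes, against a median of 0.10 for immediate early genes and against a mean of 0.00 for the unfolded protein list. In edgeR 272 genes had an unadjusted p under 0.05. DESeq2 placed 4 genes past the threshold (IL1RN, DHRS2, KDR and PDE2A) and limma-voom 1. The edgeR fit of the compared groups alone placed 4 past it (IL1RN, DHRS2, KDR and CRISPLD2). Within the CV41 libraries, with 2 libraries in each group, IL1RN stood at log2 3.52 ± 0.33 (adjusted p = 0.00383); the CV42 libraries hold 1 of each group and allow no test.

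**Figure D3:**
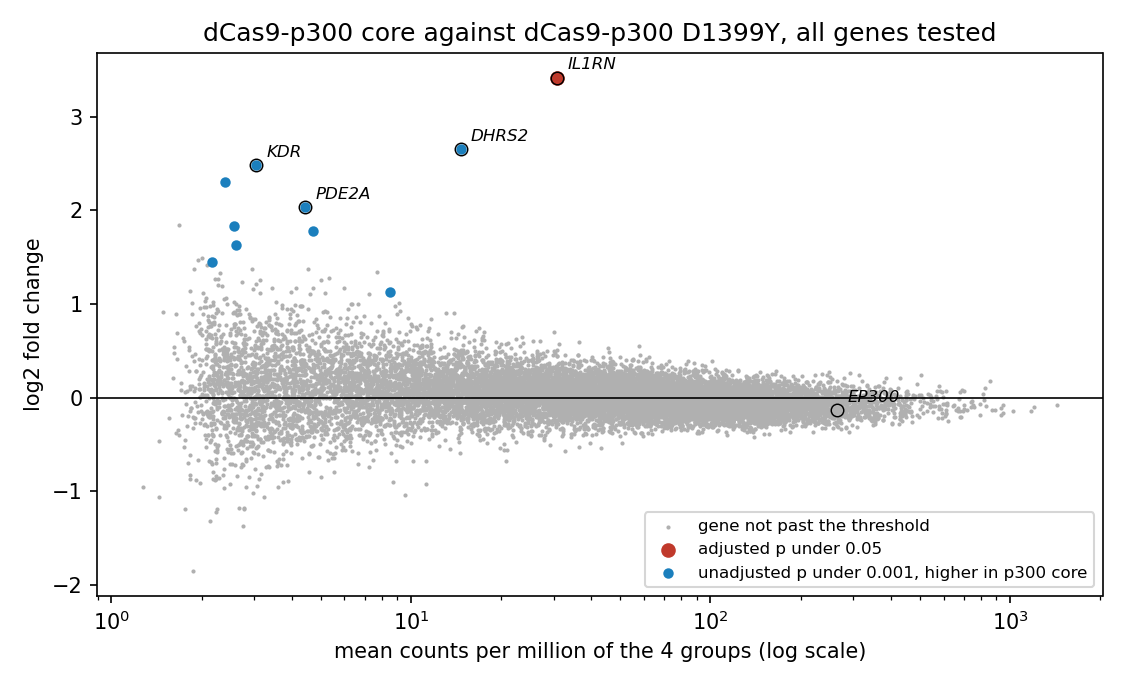
Log2 fold change of the core over D1399Y (vertical axis) against mean level (CPM, log scale) for each of 14613 genes, in red where the adjusted p passed and in blue where the unadjusted p was under 0.001 with a higher level in the core. IL1RN is the 1 red point, at 3.42, and EP300 lies near 0, at -0.14.

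The comparison of dCas9-p300 core with dCas9-VP64 sets the acetyltransferase core beside the activation domain at the same sites. IL1RN was 3.38-fold higher with the core (95% interval 2.44 to 4.68; log2 1.76 ± 0.22; adjusted p = 0.0215, edgeR), in 3 of 3 libraries, and was the 1 gene past the threshold. KDR was 6.47-fold higher without passing (log2 2.69 ± 0.40, adjusted p = 0.0797). Also higher without passing were EP300 (log2 1.58 ± 0.26, adjusted p = 0.160), CRISPLD2 (log2 2.04 ± 0.35, adjusted p = 0.160), NFASC (log2 1.37 ± 0.26, adjusted p = 0.356) and VSIR, the T cell checkpoint protein VISTA (log2 2.32 ± 0.45, adjusted p = 0.404). This fit estimates the spread over all groups, the dCas9 libraries among them. In an edgeR fit of the compared groups alone 6 genes passed, EP300 (adjusted p = 8.37e-07), IL1RN, KDR, CRISPLD2, VSIR and CYRIA.

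Camera placed 2 of 20 lists higher with the core than with dCas9-VP64 and 1 lower. Cholesterol synthesis genes had 14 of 14 members above 0 and a median log2 of 0.11, with DHCR7, the last enzyme of the pathway, at 0.27 ± 0.13 (adjusted p = 0.0208; adjusted p = 0.754 with an estimated correlation). The endothelial list had 3 of 3 members above 0 and a median of 0.50, with EMCN at 0.50 ± 0.35 (adjusted p = 0.000731; adjusted p = 0.0717 with an estimated correlation), and KDR was its 1 member past the threshold adjusted over the list alone (adjusted p = 3.27e-05). Targets of p53 had 2 of 18 members above 0 and a median of -0.18, with the antiproliferative gene BTG2 at -0.52 ± 0.18 and the oxidoreductase gene TP53I3 at -0.86 ± 0.49 (adjusted p = 0.000731; adjusted p = 0.422 with an estimated correlation). With fry the smallest adjusted p was 0.0662. The median log2 ratio to the mean of the 12 libraries was 0.38 for p53 targets in dCas9-VP64 replicate 1 and -0.25 for cholesterol synthesis genes in dCas9-VP64 replicate 2. In core replicate 3 it was -0.28 for p53 targets, 0.18 for cholesterol synthesis genes and 0.56 for the endothelial list. The p53 call was lost without dCas9-VP64 replicate 1, at a median of -0.08, and the cholesterol call without dCas9-VP64 replicate 2, at 0.04. Both were lost without core replicate 3, at -0.10 and 0.04, and within the CV41 libraries, at the same rounded medians. The endothelial call was kept both times, at a median of 0.19. Ribosomal protein genes were called lower without core replicate 1 or dCas9-VP64 replicate 3, at medians of -0.15 and -0.11. Their median turned to 0.04 without core replicate 2, with 5 of 30 members below 0. With offsets for length and GC content it was 8e-04, with 15 of 30 below 0. Other lists called higher were fibroblast markers without dCas9-VP64 replicate 2, at 0.36, hypoxia targets without core replicate 2, at 0.16, and immediate early genes without dCas9-VP64 replicate 3, at 0.28. The test direction differed in sign from the mean for heat shock genes (0.02), histone genes (-0.05) and neuronal markers (0.02), and from the median for deacetylases (0.00), interleukin 1 receptor signalling (-0.01) and keratinocyte markers (0.28).

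Which libraries were used decided whether IL1RN passed between the core and dCas9-VP64. Its log2 fold change stayed between 1.61 and 1.96 with 1 library left out, and it missed the threshold without dCas9-VP64 replicate 1 (adjusted p = 0.329) or 2 (adjusted p = 0.298) and without core replicate 1 (adjusted p = 0.0725), 2 (adjusted p = 0.238) or 3 (adjusted p = 0.216). Within the CV41 libraries it stood at log2 1.71 ± 0.26 (adjusted p = 0.398), and the CV42 libraries hold none of the dCas9-VP64 group. In edgeR 309 genes had an unadjusted p under 0.05, while DESeq2 placed 5 genes past the threshold (IL1RN, EP300, KDR, CRISPLD2 and NFASC) and limma-voom 1.

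IL1RN was 3.17-fold higher with dCas9-VP64 than with D1399Y (95% interval 2.16 to 4.63; log2 1.66 ± 0.26), in 3 of 3 libraries, without passing over all genes (adjusted p = 0.119, edgeR). Adjusted over the 6 IL1RN comparisons, its adjusted p was 1.81e-05. DESeq2 placed it past the threshold (adjusted p = 1.37e-05), and over all alternatives its adjusted p ran up to 1.00.

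Against dCas9, edgeR called 1 gene for the core and 0 for D1399Y. The shared calls and n1 × n2 / N were therefore bound to be 0, which tests nothing. With DESeq2 and with limma-voom the calls shared 1 gene, EP300. Across 14613 genes, which are not independent replicates, the log2 fold changes of the core and of D1399Y correlated at 0.677. In 30 simulations of unchanged groups that share the dCas9 libraries the correlation was 0.740 to 0.763. The covariance was 0.0593, below the simulated 0.0724 to 0.0791. Without dCas9 replicate 3 the covariance was 0.0359, where 30 simulations of the remaining libraries gave 0.0499 to 0.0531. The correlation was then 0.534, against 0.652 to 0.674. The simulations drew each gene and library independently, whereas same-number libraries of dCas9 and D1399Y correlated at 0.237 to 0.498. Such pairing can lower the covariance, so the gap to the simulations does not show that the fusions share less than unchanged groups.

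dCas9 replicate 3 differed from the other libraries over the whole transcriptome. It lay at 80.3 on the first principal component, which held 44.8% of the variance, and no other library lay as high. The SD of its log2 ratios was 0.713, against 0.184 to 0.386 elsewhere. Its ratios fell from a median of 0.53 in the shortest of 10 length classes to -0.95 in the longest, with a rank correlation with length of -0.669 across genes. Its EP300 level was 51.9 CPM, against 124 CPM and 146 CPM in replicates 1 and 2 of dCas9.

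**Figure D4:**
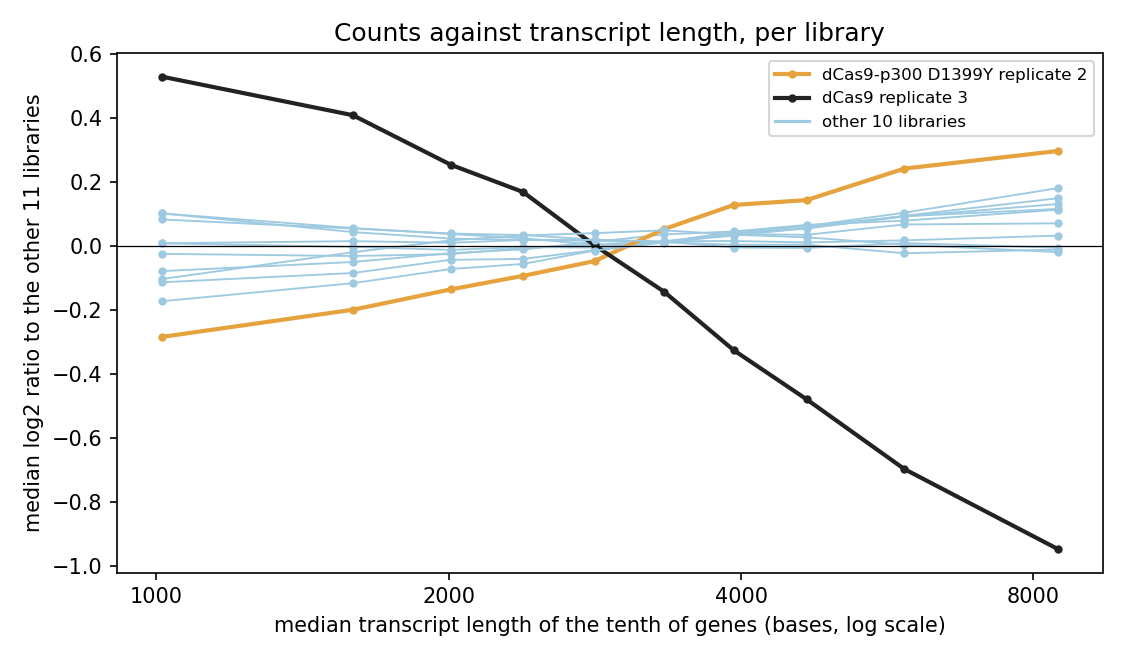
Median log2 ratio of each library to the other libraries in 10 classes of transcript length, from the shortest to the longest. dCas9 replicate 3 runs from 0.53 to -0.95, and D1399Y replicate 2 runs the other way, from -0.28 to 0.30.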

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

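Each group held 3 libraries, and a p that misses the threshold does not show equal levels. The pool label CV42 falls only on replicate 3 of both p300 groups, so pool and group cannot be separated within it. The counts rest on hg19 and the names on GRCh38, and the duplicate handling and the counting rule are not given in the sources used here. The robust quasi-likelihood fit, limma-voom with quality weights, the length and GC offsets, the fit without ribosomal RNA and the fit of single transcripts were added after the data were examined. Where a value below moved with a setting, the cause was not tested.

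IL1RN kept its direction and its call under all 20 alternatives, left-out libraries among them, for the core against dCas9 (log2 3.58 to 3.94 apart from left-out libraries; adjusted p from 2.72e-35 to 0.00555) and for the core against D1399Y (log2 3.38 to 3.52, likewise; adjusted p from 2.84e-33 to 0.00383). With 1 library left out it lay between 3.40 and 3.91 and between 3.30 and 3.57. For dCas9-VP64 against dCas9 it passed with DESeq2 (1.90), without a filter (1.91), with the replicate block (1.89) and with length and GC offsets (1.98), and lay between 1.64 and 2.15 with 1 library left out; its adjusted p ran from 5.01e-07 to 0.998. For the core against dCas9-VP64 it did not pass in the CV41 libraries (1.71) or with the pool label as a covariate (1.68), and lay between 1.61 and 1.96 with 1 library left out; its adjusted p ran from 5.95e-10 to 0.398. For D1399Y against dCas9 it lay between -0.0188 without dCas9 replicate 1, where its sign reversed, and 0.49. For dCas9-VP64 against D1399Y it passed with DESeq2 (1.66; adjusted p = 1.37e-05), without a filter (1.66), in the fit of the compared groups alone (1.66) and with quality weights (1.67), and lay between 1.46 and 1.81 with 1 library left out.

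The number of genes past the threshold moved in each comparison. For dCas9-VP64 against dCas9 it was 1 with DESeq2, 1 without a filter, 1 with the replicate block, 1 with length and GC offsets, and 0 to 1 with 1 library left out. For the core against dCas9 it was 2 with RLE, 2 with upper-quartile factors, 4 with DESeq2, 2 with limma-voom, 3 without a filter, 3 with the stricter filter, 2 with quality weights, 2 with length and GC offsets, 3 genes in the fit of single transcripts, and 1 to 2 with 1 library left out. For D1399Y against dCas9 it was 1 with RLE, 1 with upper-quartile factors, 1 with DESeq2, 1 with limma-voom, 1 without a filter, 1 with the stricter filter, 1 with quality weights, 1 with length and GC offsets, 1 in single transcripts, and 0 to 1 with 1 library left out. For the core against D1399Y it was 4 with DESeq2, 4 in the fit of the compared groups alone and 7 with quality weights. For the core against dCas9-VP64 it was 2 with upper-quartile factors, 5 with DESeq2, 3 without a filter, 6 in the fit of the compared groups alone, 0 in the CV41 libraries, 0 with the pool covariate, 15 with quality weights, 4 with length and GC offsets, 2 in single transcripts, and 0 to 1 with 1 library left out.

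EP300 passed in several settings. For the core against dCas9 it stood at 1.86 with RLE, 1.85 with upper-quartile factors, 1.86 with DESeq2, 1.96 with limma-voom, 1.86 without a filter, 1.85 with the stricter filter, 1.54 with quality weights and 1.598 with length and GC offsets, and between 1.54 and 2.14 with 1 library left out; its adjusted p ran from 6.98e-08 to 0.951. For D1399Y against dCas9 it stood at 2.003 with RLE, 1.95 with upper-quartile factors, 2.01 with DESeq2, 2.10 with limma-voom, 2.0006 without a filter, 1.995 with the stricter filter, 1.80 with quality weights and 1.81 with length and GC offsets, and between 1.67 and 2.28 with 1 library left out; its adjusted p ran from 2.97e-09 to 0.822. For dCas9-VP64 against dCas9 it lay between -0.0396, without dCas9 replicate 3, and 0.57. The core and D1399Y calls shared 1 gene, EP300, with RLE, 1 with DESeq2, and 1 each with upper-quartile factors, limma-voom, no filter, the stricter filter, quality weights, length and GC offsets, and without dCas9 replicate 2 or 3, and 0 with the replicate block, the fits of the compared groups alone, the CV41 libraries, the pool covariate, the robust fit, the fit without ribosomal RNA, and without dCas9 replicate 1.

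The replicate number was not used as a block in the main test, because only 14 of 18 pairs of libraries with the same number correlated above 0.1 across genes, with a range of -0.176 to 0.498, although each of the 12 libraries correlated best with one of its own number. This was decided over all 18 pairs together. Taken by groups, all 3 pairs lay above 0.1 for dCas9 with D1399Y (0.237 to 0.498) and for dCas9-VP64 with the core (0.250 to 0.360), and 2 of 3 pairs in each of the other 4. Any effect shared by libraries of the same number stays in the spread of the main test. With the replicate block, genes at an unadjusted p under 0.05 rose from 449 to 953 for dCas9-VP64 against dCas9. For the core against dCas9 they rose from 454 to 757, and for D1399Y against dCas9 from 861 to 1569. The block gave 1 gene past the threshold for dCas9-VP64 against dCas9, IL1RN at 1.89 (adjusted p = 0.0232), and 23 gene list calls. The endothelial list for the core against dCas9 was not among them. Calls of lower were added for hypoxia targets in the core against dCas9 (median -0.14) and in D1399Y against dCas9 (-0.18), and for immediate early genes in D1399Y against dCas9 (-0.16), where the block raised the calls from 3 to 5 lists. Over all comparisons camera made 21 gene list calls, 0 of them with an estimated correlation and 0 with fry, and 9 to 23 calls with 1 library left out, the fewest without dCas9 replicate 1.

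The other genes named in the text gave 95 results, compared in 1898 pairs of a result and a setting. In 1841 pairs the sign and the side of the threshold stayed the same, 33 became stronger and 24 changed sign. Staying the same does not mean a stable value. COL6A3 for the core against dCas9 counts as the same throughout and lay between 1.06 and 3.00 with 1 library left out. For the core against dCas9, length and GC offsets reversed BPTF (-0.11), FLT1 (-0.0157), TTL (-0.30), POU5F1 (0.0253), POLR1B (-0.0132) and CHCHD5 (0.0514), and RPS9 (0.0803) for D1399Y against dCas9. Quality weights reversed FLT1 (-0.0250), CDH1 (-0.14), TNFAIP3 (-0.10), POU5F1 (0.20) and TP53I3 (0.42), and upper-quartile factors ZNG1B (-0.0012). With 1 library left out, values for the core against dCas9 lay between -0.0348 and 0.46 for BPTF, -0.13 and 0.42 for FLT1, -0.0872 and 0.50 for CDH1 (with -0.0585 also reversed), -0.33 and 0.17 for POU5F1, -1.12 and 0.32 for TP53I3, -0.13 and 0.90 for PSD4, -0.0451 and 0.41 for CKAP2L, -0.0664 and 0.25 for POLR1B, and -0.0917 and 0.21 for ZNG1B.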

Other observations

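At an unadjusted p under 0.001, 9 genes besides IL1RN were higher in the core than in D1399Y and 0 were lower. By chance 14.6 of the 14613 genes would reach that p. At an unadjusted p under 0.05 there were 272 genes, where 730.7 would be expected. Counts in this fit thus fell short of the expectation in general, which does not show that the 9 genes arose by chance. CRISPLD2 had mean levels of 3.37, 2.44, 10.2 and 2.92 CPM with dCas9, dCas9-VP64, the core and D1399Y, PDE2A 2.97, 2.70, 9.73 and 2.36 CPM, and DHRS2 13.2, 8.97, 31.5 and 4.94 CPM. KDR counts were 27, 46 and 34 in the core libraries and at most 8 in any other. In the main edgeR fit none of the 9 genes passed over all genes. DESeq2 placed DHRS2, KDR and PDE2A past the threshold, and the edgeR fit of the compared groups alone DHRS2, KDR and CRISPLD2. With limma-voom and quality weights CRISPLD2, VSIR, KDR, DHRS2 and PDE2A passed.

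Of the tests on dCas9 replicate 3, those on length and GC content were chosen only after results were seen. A trend with length and GC content held 55.15% of the variance of its log2 ratios, against 56.12% in D1399Y replicate 2, so the size of the share cannot tell it apart. With the trend removed the SD of its ratios was 0.4777, above the 0.3232 that was the highest elsewhere, so this trend does not hold all of its spread. Length and GC content were averages over GRCh38 transcripts, and depth was not made equal here. Composition as the whole cause is therefore not excluded. With the deposited counts of all libraries thinned to its total, its SD stayed at 0.7263, against 0.4298 at most elsewhere. Fewer counts alone therefore do not account for the spread of its ratios. If reads were limited before counting, thinning afterwards cannot reproduce a lower depth, so depth is not excluded in that case. A mislabelled dCas9-VP64 or core library is unlikely, as its IL1RN level was 9.261 CPM (upper counting bound 13.67 CPM) against 19.34 CPM in the lowest dCas9-VP64 library (lower bound 15.24 CPM), and a p300 fusion library is excluded by EP300 at 51.86 CPM (upper bound 61.2 CPM).

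For the 9 genes higher in the core than in D1399Y, which were selected on the same data, the test on a single core library and the fit with length and GC offsets were chosen only after results were seen. Chance selection of noisy genes and a single core library carrying the difference were tested together. Genes were chosen anew without 1 core library at a time and read in that library over dCas9-VP64. The genes so chosen shared 6, 6 and 7 members with the 9 genes. Their lowest median log2 ratio was 1.4884, with 7 of 7, 6 of 6 and 8 of 9 above 0. Neither accounts for the genes so chosen as a set. Any of the 9 genes not chosen again was not tested in this way. Length and GC composition does not account for the 9 genes as a set, since their median was 1.8578 with those offsets. Binding of dCas9 at these genes was not analysed here.

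Of the tests on EP300, those on the transfected core and on catalytic activity were chosen only after results were seen. The lowest p300 fusion library had 339.4 CPM against 145.6 CPM in the highest of the other libraries. Whether reads of the transfected p300 core were counted to EP300 stays open, because that difference is the observation itself and no test of it. The core and D1399Y differed by log2 -0.1354, so catalytic activity does not account for the higher counts with D1399Y, which lacks that activity. Because the counts can include reads of the plasmid, a rise of the cell's own EP300 with the core is not excluded. Reads shared with the paralog CREBBP would raise it too, and its larger fold change was log2 0.2816.

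No test on the splits was chosen after its result was seen. The 6 libraries of a comparison split in 10 ways into 3 and 3, too few for a share under 0.05. Where 0 genes passed in the real split, every split was bound to give as many, which tests nothing. Where 1 split is given, it is the real split itself. As many genes passed as in the real split in 10 of 10 splits for dCas9-VP64 against dCas9 (real 0, highest other 0), in 1 for the core against dCas9 (real 1, highest other 0), in 10 for D1399Y against dCas9 (real 0, highest other 0), in 1 for the core against D1399Y (real 1, highest other 0) and in 1 for the core against dCas9-VP64 (real 1, highest other 0).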
